A study of Mus musculus with 12 samples.

How the data were processed

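The data are 12 hippocampus RNA sequencing libraries of C57BL/6 mice in 4 groups of 3, taken from the sample titles: unstressed or exposed to chronic unpredictable stress (CUS), with 7 days of RVG-tagged extracellular vesicles holding circDYM or the vector. Per the labels' protocols, poly(A) RNA was selected, the second strand was marked with dUTP and removed, adapters carried unique molecular identifiers, and libraries were sequenced in paired ends on an Illumina NovaSeq. HISAT, StringTie and edgeR and the mouse build mm9 are named in the submitters' processing notes, with versions not given in the sources used here. Whether the molecular identifiers were used to remove PCR duplicates, and whether counting used the strand, is likewise not given in the sources used here.

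The deposited table has 34921 genes and holds, per the file headers, FPKM and counts for each library. The deposited counts are whole numbers and were read as estimated counts made by the authors, because StringTie derives counts from coverage. For genes with 1 transcript, 96.4% of 18374 values had a ratio of count to FPKM times transcript length within 2% of the library's constant. The authors' FPKM values are scaled for gene length and library size, and were used only in alternative fits and in the rule for named genes. Of 34807 genes matched by ID to GENCODE release M21 of GRCm38, 31835 had equal coordinates (91.5%), so the coordinates printed are the file's and are not those of mm9.

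Estimated counts were rounded to whole numbers, which changed none of them. Library totals ran from 37140657 to 47113072, and 3 counts over the unstressed vector group correspond to 0.0237 CPM. Floors cover counting error only. Genes were kept by edgeR's filterByExpr (21233 genes) and scaled by TMM. One quasi-likelihood model with a mean for each of the 4 groups was fitted over all 12 libraries with glmQLFit and tested with glmQLFTest, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The common biological coefficient of variation was 0.213. The design written in advance assumed FPKM tested with limma, with the edgeR test to replace it if counts were present, which was done.

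The comparisons were stress under vector EVs, circDYM EVs under stress, circDYM EVs without stress, their interaction, and the averages over stress states and over EV types. The remaining pairs of groups were tested in the same fit after the data were seen. CPM are on TMM-scaled library sizes, given as mean ± SD, and log2 fold changes are edgeR's with a standard error computed from the test statistic. A group with 0 counts was set to 3 counts over the group, and the fold is then a lower bound.

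There were 33 gene lists of pathways and of cell types that a hippocampal dissection can hold, fixed before the data were examined, as were the comparisons and the alternatives, except for those named as added. Lists of at least 5 tested genes were compared with all other genes by limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation. With the estimate, the called lists dropped from 11 to 2 for stress, from 7 to 0 for circDYM under stress, from 11 to 4 without stress, from 7 to 2 for the interaction, and from 16 and 13 to 0 for the averages. No called list had a median, mean and test that differed in sign. KEGG and GO terms of the file's own annotation, with 10 to 500 genes in the background, were tested with Fisher's exact test against annotated tested genes (6195 for KEGG with 307 terms and 15729 for GO with 2266 terms), a step chosen after the data were seen.

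The named genes are, for each of 4 comparisons, the 10 largest rises and falls among the calls. They need an FPKM of at least 1 in one group and, except for the interaction, all 3 libraries of one group above all 3 of the other, which chance gives in 10% of genes. Added to them are the members of each list with the lowest p, and Dym and Taf1 always. Genes named by this rule that share reads with near copies, such as the Pcdhga cluster, Tgtp1 and Tgtp2, the globins and Hspa1a and Hspa1b, are uncertain.

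Comparisons that share libraries were set against 1000 simulations of unchanged groups drawn from the residual spread of each gene and tested by limma on log2 CPM, and the correlations under each alternative against 1000 simulations of that fit. The test was checked on a single draw of simulated counts for the stress comparison over 21233 genes, with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. The draw used edgeR's own dispersions of the data. edgeR recovered 29.9%, 58.2% and 69.7% of them, and 2.8% of its calls were unchanged genes. DESeq2 recovered 37.3%, 71.6% and 72.7% with 24.4% unchanged genes among its calls, and limma on log2(FPKM + 1) recovered 11.9%, 43.3% and 63.6% with 1.2%. No replicate pair held identical values or agreed within sampling noise, with chi-square values per degree of freedom between 24.0 and 53.0.

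Alternatives were DESeq2 and its size factors, limma on FPKM with other pseudocounts, scalings or a robust fit, other filters, median centring, a replicate block, the 6 compared libraries alone, another threshold and each library left out. In a comparison of 2 groups, leaving out a library of another group changes only the shared spread, the genes kept and the scaling. Added after the data were seen were a fit without unstressed vector replicates 1 and 3 and a choroid plexus covariate. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.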

Results

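Gene expression was measured by strand-marked, poly(A)-selected RNA sequencing in 12 hippocampus libraries from C57BL/6 mice, 3 in each of 4 groups. The groups cross chronic unpredictable stress (CUS), a rodent protocol of varied stressors used to model depression, with the cargo of extracellular vesicles (EVs) given for 7 days. The EVs carried a peptide of the rabies virus glycoprotein (RVG), which is used to direct vesicles to neurons, and held either circDYM, a circular RNA made from the Dym gene, or the vector. The groups are named unstressed vector, unstressed circDYM, CUS vector and CUS circDYM. The sample titles use the same control word for stress and for EVs, and in the second place it was read as vector EVs. Estimated counts summed to between 37140657 and 47113072 per library (mean 43202967 ± 2744698, SD, n = 12 libraries), and transcripts of the mitochondrial genome took 6.93% ± 0.35 of them (SD, n = 12). The labels do not say that the replicates are separate mice, so p-values measure the spread between these samples, which may be technical. The comparisons, the gene lists and the rule for named genes were chosen before the data were examined.

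Some libraries stood apart in cell content. Ttr, the transthyretin gene that choroid plexus epithelium expresses strongly, lay at 15.6 CPM (counts-per-million) in unstressed vector replicate 1 and between 774 and 3756 CPM in all other libraries. Hbb-bs, a beta-globin gene of red blood cells, lay at 61.2 CPM in unstressed vector replicate 3 and between 1.08 and 6.99 CPM elsewhere, and its reads can be shared with the other globin copies. Dym itself (ENSMUSG00000035765, chromosome 18, 75018781 to 75286964) lay at 39.4 ± 3.73, 39.0 ± 1.45, 40.9 ± 0.941 and 39.2 ± 2.09 CPM in the unstressed vector, unstressed circDYM, CUS vector and CUS circDYM groups (mean ± SD, n = 3 libraries each). It passed the test in no comparison (adjusted p = 0.765 for stress, 0.774 for circDYM under stress, 0.964 for circDYM without stress). Poly(A) selection does not retain circular RNA, so these values are of the linear Dym transcript and circDYM was not measured. Coordinates are those of the file and match the GRCm38 annotation for 91.5% of the genes matched by ID, although the submitters' processing notes name mm9.

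Of the 6 pairs of groups, the CUS vector group differed most from the others. Against the unstressed vector group it had 896 genes higher and 416 lower, against the CUS circDYM group 327 higher and 175 lower, and against the unstressed circDYM group 315 higher and 174 lower. The unstressed circDYM group had 111 genes higher and 25 lower than the unstressed vector group, and the CUS circDYM group 57 higher and 10 lower. Between the CUS circDYM and unstressed circDYM groups edgeR's quasi-likelihood test called 0 genes. There, 973 genes had an unadjusted p under 0.05 where 1062 are expected by chance, limma on FPKM called 0 genes and DESeq2 called 22. The 896 genes that rose with stress under vector EVs had a median log2 fold change of 0.45 in that comparison and of -0.02 between the 2 circDYM groups, where 393 kept the same sign. The 416 genes that fell had medians of -0.44 and 0.03, and 170 kept the sign.

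**Figure D1:**
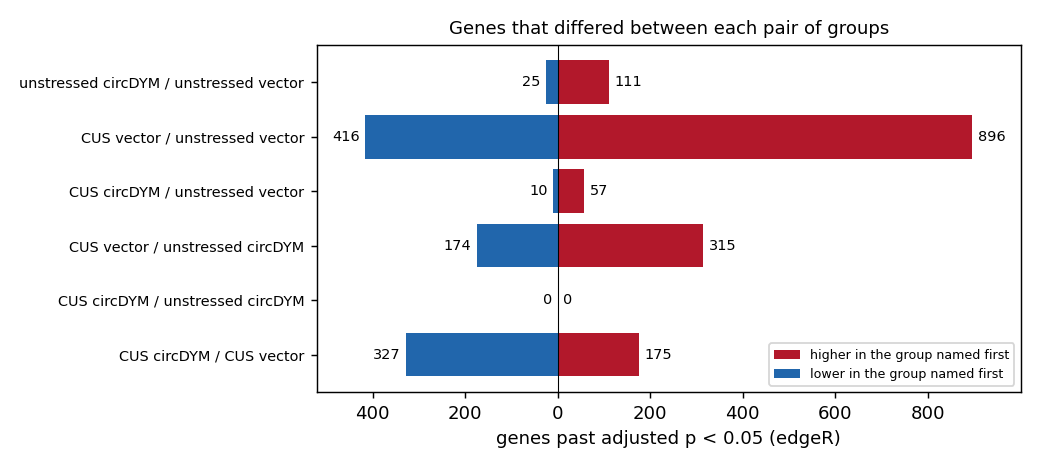
Number of genes past an adjusted p of 0.05 (horizontal axis) for each pair of groups, with genes higher and lower in the first-named group drawn to either side. CUS vector against unstressed vector has the longest bars, 896 and 416 genes, and the pair of circDYM groups has 0 by edgeR.

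The comparison of CUS vector with unstressed vector libraries asks what stress changed in the hippocampus. Genes that respond to glucocorticoids, the adrenal stress hormones, rose: 18 of 22 tested members of that list were higher and the rest did not pass (20 higher and 1 lower adjusted over the list alone). Plin4, a lipid droplet coat protein gene (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803), rose 17.8-fold, from 3.21 ± 0.30 to 57.2 ± 4.97 CPM (mean ± SD, n = 3; log2 fold change 4.15 ± 0.25 SE, adjusted p = 6.59e-05). Sult1a1, a sulfotransferase gene, rose 3.18-fold (1.67 ± 0.11, adjusted p = 8.55e-05), and Fkbp5, whose product restrains the glucocorticoid receptor, rose 1.89-fold (0.92 ± 0.08, adjusted p = 0.000231). Sgk1, a kinase gene (ENSMUSG00000019970, chromosome 10, 21882184 to 21999893), went from 69.4 ± 8.23 to 190 ± 14.5 CPM (1.45 ± 0.14, adjusted p = 0.000413). The list's median log2 fold change was 0.99 (camera adjusted p = 1.78e-23, and 0.0313 with an estimated correlation).

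Heat shock proteins and chaperones rose with stress as well, with 12 of 20 tested members higher (18 adjusted over the list alone). Hspa5, the main Hsp70 chaperone of the endoplasmic reticulum (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), rose 2.25-fold, from 164 ± 21.5 to 368 ± 54.8 CPM (1.17 ± 0.12, adjusted p = 0.000514). Hspb1, a small heat shock protein gene, rose 3.55-fold (adjusted p = 0.000562) and Hsph1, of the Hsp110 family, 1.54-fold (adjusted p = 0.000171). The median was 0.41 (camera adjusted p = 9.99e-19, and 0.0313 with an estimated correlation). Among KEGG pathways, tested after the data were seen, protein processing in the endoplasmic reticulum held 31 of the higher genes where 9.57 are expected (adjusted p = 9.93e-07).

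Interferon-response genes were higher in the CUS vector group, 13 of 24 tested members at the threshold (19 adjusted over the list alone) and with a median of 1.10 (camera adjusted p = 6.19e-13, and adjusted p = 0.196 with an estimated correlation). Gbp2, a guanylate-binding protein gene of cell-autonomous immunity (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), rose 7.60-fold, from 4.63 ± 1.39 to 35.2 ± 24.1 CPM (2.93 ± 0.47, adjusted p = 0.00497), and by 2.31 on the log2 scale without CUS vector replicate 2. CUS vector replicate 1 stood below the others of its group, with Gbp2 at 11.1 CPM against 59.3 and 35.3 in replicates 2 and 3. Ifitm3, a membrane protein gene that restricts virus entry, rose 2.48-fold (adjusted p = 0.00278), and Stat2, a transcription factor of the interferon receptor pathway, 1.72-fold (adjusted p = 0.00653). The MHC class I and antigen presentation list had 3 of 18 members higher (10 adjusted over the list alone), among them the complement gene C4b, 1.61-fold (adjusted p = 0.0104). Its median was 0.66 (camera adjusted p = 1.09e-06, and adjusted p = 0.34 with an estimated correlation). Of the reactive astrocyte genes, 7 of 20 rose, with or without adjustment over the list alone. They include the iron-binding lipocalin gene Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32387797), from 0.725 ± 0.695 to 27.8 ± 10.7 CPM (log2 fold change 5.24, adjusted p = 0.000825, and 6.41 without unstressed vector replicate 3), and the oncostatin M receptor gene Osmr, 2.38-fold (adjusted p = 0.00283). Their median was 0.37 (camera adjusted p = 5.94e-06, and adjusted p = 0.152 with an estimated correlation). The lists overlap: Lcn2 is also in the glucocorticoid-responsive list, Hspb1 in the heat shock list and Iigp1 in the interferon-response list. All of these rose with stress, so they are counted in more than 1 list.

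Immediate early genes, which neurons transcribe within minutes of activity, had 9 of 25 members higher and 1 lower with stress (14 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 4.74e-08, and adjusted p = 0.196 with an estimated correlation). Fos rose 2.04-fold (adjusted p = 0.00327) and Dusp1, a phosphatase gene, 1.83-fold (adjusted p = 0.000876). Of the clock genes 4 of 16 rose, among them Per3, 1.60-fold (adjusted p = 0.00134), with a list median of 0.28 (camera adjusted p = 0.00319, and adjusted p = 0.196 with an estimated correlation; 8 higher and 1 lower adjusted over the list alone). Markers of dentate granule cells split into 5 higher and 1 lower of 12, the same counts as adjusted over the list alone. Glis3, a zinc finger gene, rose 1.5-fold (adjusted p = 0.005), Pla2g4e, a phospholipase gene, fell 2.76-fold (adjusted p = 0.0024), and the median was 0.18 (camera adjusted p = 0.00927, and adjusted p = 0.653 with an estimated correlation). The dentate list lost its camera call without unstressed vector replicate 3 (adjusted p = 0.102) and without CUS vector replicate 1 (adjusted p = 0.114). Mural cell markers had 3 of 14 lower, with or without adjustment over the list alone (median -0.21, camera adjusted p = 0.0267, and adjusted p = 0.34 with an estimated correlation). That call was lost without unstressed vector replicate 2 (adjusted p = 0.0624) and without CUS vector replicate 2 (adjusted p = 0.0867).

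Vessel and oligodendrocyte markers moved both ways with stress, and neither list passed the camera test. Of 22 endothelial and blood-brain barrier markers 4 rose and 5 fell (6 and 6 adjusted over the list alone; median -0.01, camera adjusted p = 0.996). Slc2a1, the glucose transporter of the blood-brain barrier, rose 1.8-fold (adjusted p = 0.000348). Kdr, the main receptor for vascular endothelial growth factor (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458), fell from 24.2 ± 1.64 to 10.8 ± 1.49 CPM (log2 fold change -1.17 ± 0.11, adjusted p = 0.000422). Tek, the angiopoietin receptor gene, fell 1.75-fold (adjusted p = 0.000843). Of 20 oligodendrocyte and myelin markers 2 rose and 2 fell (3 and 3 adjusted over the list alone; median -0.14, camera adjusted p = 0.544). Opalin, a myelin paranode protein gene, fell 2.38-fold (adjusted p = 0.00118) and Anln, the anillin gene, rose 1.54-fold (adjusted p = 0.00122). Outside the lists, Hes5, a target of Notch signalling (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371), fell 2.21-fold, from 6.86 ± 0.749 to 3.10 ± 0.277 CPM (adjusted p = 0.00129). Scgb3a1, a secretoglobin gene, had 0 counts in the unstressed vector libraries and 141 over the CUS vector libraries, at least 44.3-fold higher against a floor of 3 counts over the group.

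In all, edgeR's quasi-likelihood test called 1312 of 21233 genes between the CUS vector and unstressed vector groups at a Benjamini-Hochberg adjusted p of 0.05, with a median absolute log2 fold change of 0.45 among the calls, and 211 of them changed at least 2-fold. The count was 655 without unstressed vector replicate 2, 800 without CUS vector replicate 1, 621 without CUS vector replicate 2 and 2178 with DESeq2. DESeq2 also called more unchanged genes in a single simulation drawn with edgeR's dispersions, which cannot show whether its further calls in the data are false. Each gene named above for this comparison passed in all 12 fits that left out 1 library, except that Sgk1, which the rule names in another comparison, was not followed through them. These genes are only a part of those that the rule names. Of the 79 that it names here and that passed, 49 passed in all 12 fits and 30 lost the call in at least 1. Red blood cell markers, with a median of -3.18 (camera adjusted p = 0.0267, and adjusted p = 0.653 with an estimated correlation), lost the call without unstressed vector replicate 3 (adjusted p = 0.316), the library with high Hbb-bs, and without CUS vector replicates 2 and 3 (adjusted p = 0.0867 and 0.103). Mitochondrially encoded mRNAs, whose share can follow RNA quality, had a median of -0.08 over 13 genes, none of which passed (camera adjusted p = 0.0226, and adjusted p = 0.811 with an estimated correlation). That list lost its call without unstressed vector replicate 1 (adjusted p = 0.495) and without CUS vector replicate 1 or 2 (adjusted p = 0.0762 each).

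The comparison of CUS circDYM with CUS vector libraries asks what circDYM EVs changed in stressed mice. Of the 8 lists called higher with stress, 6 were called lower here, and the immediate early and clock lists were not. Both comparisons use the CUS vector libraries, with opposite sign. Anything peculiar to those libraries would raise a list with stress and lower it here without an effect of circDYM EVs. No simulation covered the lists, so how much of the reversal this gives is not known. Immediate early genes had a median of 0.15, with 3 of 25 higher and 1 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.06), and clock genes a median of 0.07, with 2 of 16 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.116). Of the heat shock proteins 7 of 20 fell (11 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 4.06e-11, and adjusted p = 0.257 with an estimated correlation). Hsph1 fell 1.33-fold (adjusted p = 0.00405) and Hsp90b1, an Hsp90 of the endoplasmic reticulum, fell from 442 to 293 CPM, 1.51-fold (adjusted p = 0.0042). Of the glucocorticoid-responsive genes 4 of 22 fell (13 lower and 1 higher adjusted over the list alone; median -0.39, camera adjusted p = 4.41e-08, and adjusted p = 0.337 with an estimated correlation). Plin4 fell 6.85-fold, from 57.2 ± 4.97 to 8.35 ± 0.799 CPM (n = 3; adjusted p = 0.00162), Sult1a1 1.90-fold (adjusted p = 0.00327) and Fkbp5 1.47-fold, from 128 ± 12.4 to 86.6 ± 6.30 CPM (adjusted p = 0.00751). Sgk1 did not pass, at 190 ± 14.5 and 169 ± 14.5 CPM (log2 fold change -0.17 ± 0.14, adjusted p = 0.633). Each gene that this paragraph names as fallen passed in all 12 fits that left out 1 library.

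The interferon-response, MHC class I and reactive astrocyte lists were also lower with circDYM EVs under stress. The list of inflammatory mediators and activated microglia was not. Of its 27 tested members 1 was higher (2 higher and 1 lower adjusted over the list alone, median -0.08, camera adjusted p = 0.704). With stress under vector EVs that list had 2 higher and 1 lower (camera adjusted p = 0.544). Of 24 interferon-response genes 3 fell (7 adjusted over the list alone; median -0.53, camera adjusted p = 4.07e-05, and adjusted p = 0.63 with an estimated correlation). Gbp2 fell 5.61-fold (-2.49, adjusted p = 0.023), to 6.28 ± 0.323 CPM (n = 3). Of 18 MHC class I and antigen presentation genes 2 fell (13 adjusted over the list alone; median -0.60, camera adjusted p = 3.94e-08, and adjusted p = 0.506 with an estimated correlation). Of 20 reactive astrocyte genes 4 fell (7 adjusted over the list alone; median -0.28, camera adjusted p = 0.000125, and adjusted p = 0.337 with an estimated correlation). C1qa, which encodes a chain of complement C1q and marks microglia, fell 1.39-fold (adjusted p = 0.00405) and passed in all 12 fits that left out 1 library. The microglia identity list was not called, with 2 of 22 lower (2 higher and 4 lower adjusted over the list alone, median -0.04, camera adjusted p = 0.109). Gbp2 lost its call without CUS vector replicate 2 (log2 fold change -1.88, adjusted p = 0.0671) and without CUS circDYM replicate 1, 2 or 3 (adjusted p = 0.0937, 0.0769 and 0.097).

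Dentate granule cell markers had 4 of 12 members lower and 1 higher (8 and 1 adjusted over the list alone; median -0.31, camera adjusted p = 1.02e-05, and adjusted p = 0.51 with an estimated correlation). The CA3 marker Nptx1, a neuronal pentraxin gene, fell 1.32-fold, from 912 to 689 CPM (adjusted p = 0.00506). Its list was not called, with 1 of 12 lower, with or without adjustment over the list alone (median -0.06, camera adjusted p = 0.288). The genes that rose under stress with circDYM EVs include Hes5, 2.68-fold, from 3.10 ± 0.277 to 8.31 ± 1.08 CPM (n = 3; log2 fold change 1.42 ± 0.14, adjusted p = 0.00178). Kdr rose 1.70-fold, from 10.8 ± 1.49 to 18.3 ± 1.5 CPM (adjusted p = 0.00874), Tek 1.57-fold (adjusted p = 0.00698), and Pcsk1, a prohormone convertase gene of neuroendocrine cells, 1.77-fold (adjusted p = 0.00506). The endothelial list was not called, with 2 of 22 higher and 1 lower (5 and 7 adjusted over the list alone, median -0.10, camera adjusted p = 0.7). The nuclear-encoded oxidative phosphorylation list had a median of 0.06 over 45 genes (camera adjusted p = 0.00355, and adjusted p = 0.63 with an estimated correlation), and no single member passed edgeR's test over all genes or adjusted over the list alone. By KEGG annotation, protein processing in the endoplasmic reticulum held 16 of the lower genes where 3.68 are expected (adjusted p = 0.000192).

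In all, edgeR called 175 genes higher and 327 lower with circDYM EVs under stress, 502 of 21233. The split was 271 higher and 313 lower with limma on FPKM. The count was 233 without CUS vector replicate 1, 128 without CUS vector replicate 2, 121, 178 and 117 without CUS circDYM replicates 1, 2 and 3, and 1247 with DESeq2. Of the 54 genes that the rule names here and that passed, 15 passed in all 12 fits that left out 1 library, among them Plin4, Fkbp5, Hsph1, Hsp90b1, Nptx1, Hes5, Kdr, Tek and Pcsk1.

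The comparison of unstressed circDYM with unstressed vector libraries asks what circDYM EVs changed in the absence of stress. Immediate early genes rose, 10 of 25 tested members (20 adjusted over the list alone; median 0.67, camera adjusted p = 1.29e-24, and 0.0306 with an estimated correlation). Fos rose 2.85-fold, from 9.37 to 26.7 CPM (log2 fold change 1.51 ± 0.16 SE, n = 3, adjusted p = 0.00262) and Egr1, a zinc finger transcription factor gene, 2.03-fold (adjusted p = 0.00406). Glucocorticoid-responsive genes rose too, 13 of 22 (15 adjusted over the list alone; median 0.64, camera adjusted p = 1.29e-24, and 0.0306 with an estimated correlation). Sgk1 rose 2.57-fold, from 69.4 ± 8.23 to 178 ± 35.9 CPM (adjusted p = 0.00262), and Tsc22d3, a leucine zipper gene induced by glucocorticoids, 1.75-fold (adjusted p = 0.00775). Of the heat shock proteins 7 of 20 rose (9 adjusted over the list alone; median 0.23, camera adjusted p = 5.7e-13, and 0.0473 with an estimated correlation), among them Dnajb1, an Hsp40 co-chaperone gene, 1.60-fold (adjusted p = 0.00262). Of the clock genes 3 of 16 rose (7 adjusted over the list alone; median 0.23, camera adjusted p = 4.38e-07, and 0.0405 with an estimated correlation), with Per1, which is also glucocorticoid-responsive, 1.53-fold higher (adjusted p = 0.0084).

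Of 27 tested members of the list of inflammatory mediators and activated microglia, 4 rose with circDYM EVs without stress and the rest did not pass (5 higher and 1 lower adjusted over the list alone; median 0.19, camera adjusted p = 0.00515, and adjusted p = 0.0723 with an estimated correlation). Icam1, an adhesion molecule gene (ENSMUSG00000037405, chromosome 9, 21015985 to 21028817), rose 12.7-fold, from 3.16 ± 1.60 to 40.3 ± 19.3 CPM (log2 fold change 3.67 ± 0.44, adjusted p = 0.0056), and the cytokine gene Il1b rose 6.88-fold, from 0.283 to 1.96 CPM (adjusted p = 0.0084). Sele, the E-selectin gene of activated endothelium (ENSMUSG00000026582, chromosome 1, 164048234 to 164057677), rose from 0.123 ± 0.214 to 9.07 ± 2.41 CPM (log2 fold change 6.14 ± 0.86, adjusted p = 0.0086), and without replicate 3, the only unstressed vector library with reads of Sele, its fitted log2 fold change was 11.61, which depends on the prior count. The P-selectin gene Selp rose 34-fold, to 7.03 ± 3.86 CPM (adjusted p = 0.0091), the chemokine gene Cxcl1 37.2-fold (adjusted p = 0.0109), and Lcn2 17.7-fold, to 13 ± 4.53 CPM (log2 fold change 4.15, adjusted p = 0.0086, and 5.31 without unstressed vector replicate 3). TNF signalling, a KEGG pathway tested after the data were seen, held 10 of the higher genes where 0.95 are expected (adjusted p = 7.61e-06). The leukocyte markers beside them had a median of 0.33 over 16 genes and an upper quartile of 1.55, with 11 positive and 2 higher adjusted over the list alone but no member past the test over all genes (camera adjusted p = 0.117), and the endothelial list had 1 of 22 members higher (3 higher and 2 lower adjusted over the list alone; median 0.06, camera adjusted p = 0.559).

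Of the reactive astrocyte genes 2 of 20 rose without stress (4 adjusted over the list alone; median 0.24, camera adjusted p = 0.00115, and adjusted p = 0.243 with an estimated correlation). Choroid plexus markers had a median of 0.61 (camera adjusted p = 0.000518, and adjusted p = 0.714 with an estimated correlation), beside the low Ttr of unstressed vector replicate 1, and without that library adjusted p was 0.986. Interferon-response genes had a median of 0.17 (camera adjusted p = 0.0386, and adjusted p = 0.714 with an estimated correlation), and lost the call without unstressed vector replicate 1 (adjusted p = 0.292) and without unstressed circDYM replicate 3 (adjusted p = 0.141). Dentate granule cell markers (median -0.10, camera adjusted p = 0.037), glutamatergic synapse genes (-0.10, 0.0142) and mitochondrially encoded mRNAs (-0.05, 0.0322) lay lower than other genes, with an adjusted p of 0.714 each with an estimated correlation. No member passed over all genes, and adjusted over the list alone 1 synapse gene was higher. Without unstressed vector replicate 1 all of these calls were lost (adjusted p = 0.346, 0.346 and 0.986). The dentate call was also lost without unstressed circDYM replicates 1 and 2 (adjusted p = 0.0855 and 0.0645), the synapse call without replicate 3 (0.0661) and the mitochondrial call without replicates 2 and 3 (0.145 and 0.0661). The genes that fell include Apcdd1, an inhibitor of Wnt signalling, 1.47-fold (adjusted p = 0.00262), and the zinc finger gene Zkscan2, 1.56-fold (adjusted p = 0.00368).

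**Figure D2:**
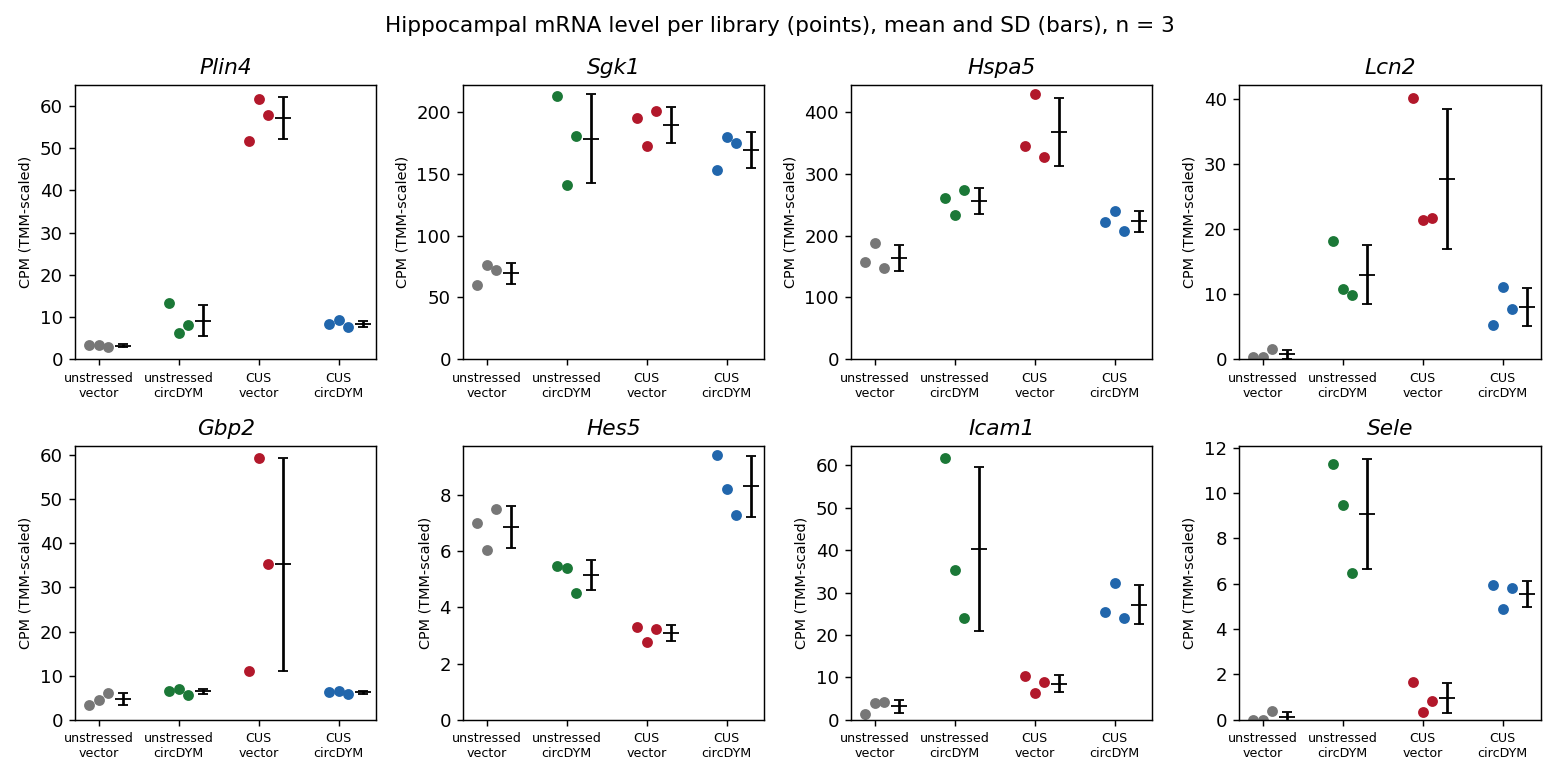
CPM of 8 genes in each library (points, linear axis), with the mean and SD of each group of 3 libraries. Plin4 averages 3.21 CPM in unstressed vector libraries, 57.2 in CUS vector and 8.35 in CUS circDYM libraries, and Icam1 averages 3.16 in unstressed vector and 40.3 in unstressed circDYM libraries.

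In all, edgeR called 111 genes higher and 25 lower with circDYM EVs without stress, 136 of 21233, and the split was 104 higher and 46 lower with limma on quantile-normalized FPKM. The count was 67 without unstressed vector replicate 1, 74 without unstressed vector replicate 2, 67 and 85 without unstressed circDYM replicates 1 and 2, and 551 with DESeq2. Each gene named above as risen or fallen in this comparison passed in all 12 fits that left out 1 library. They are only a part of those that the rule names. Of the 41 that it names here and that passed, 25 passed in all 12 fits and 16 lost the call in at least 1.

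The interaction tests whether the effect of circDYM EVs differed between stressed and unstressed mice. Its sign is negative where the effect under stress was lower than the effect without stress. By construction it is also the stress effect under circDYM EVs minus that under vector EVs. Between the circDYM groups edgeR called 0 genes, and the glucocorticoid-responsive list had a median log2 fold change of -0.04. Much of the interaction is therefore the stress effect under vector EVs with its sign turned, not a separate result. Of the glucocorticoid-responsive genes 15 of 22 had a negative interaction (20 adjusted over the list alone; median -1.14, camera adjusted p = 2.91e-23, and 0.0297 with an estimated correlation), and of the heat shock proteins 11 of 20 (16 adjusted over the list alone; median -0.51, camera adjusted p = 1.34e-19, and 0.0297 with an estimated correlation). Plin4 had an interaction of -4.28 (adjusted p = 0.000852), Sgk1 of -1.53 (adjusted p = 0.00456) and Hspa5 of -1.37 (adjusted p = 0.00372) on the log2 scale. Lcn2 had an interaction of -5.93 (-7.10 without unstressed vector replicate 3) and Ch25h, the cholesterol 25-hydroxylase gene, of -3.71 (adjusted p = 0.00561). Of the immediate early genes 4 of 25 were negative (13 negative and 1 positive adjusted over the list alone; median -0.46, camera adjusted p = 4.47e-09, and adjusted p = 0.22 with an estimated correlation), among them Fos (adjusted p = 0.00814) and Dusp1 (-1.08, adjusted p = 0.00466). Of the reactive astrocyte genes 5 of 20 were negative (6 adjusted over the list alone; median -0.49, camera adjusted p = 1.21e-06, and adjusted p = 0.11 with an estimated correlation).

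Interferon-response genes had 3 of 24 negative interactions (9 adjusted over the list alone; median -0.71, camera adjusted p = 3.59e-06, and adjusted p = 0.483 with an estimated correlation). MHC class I and antigen presentation genes had 1 of 18 (7 adjusted over the list alone; median -0.82, camera adjusted p = 4.1e-07, and adjusted p = 0.385 with an estimated correlation), and clock genes 1 of 16 (5 negative and 2 positive adjusted over the list alone; median -0.19, camera adjusted p = 0.0496, and adjusted p = 0.385 with an estimated correlation). The clock list lost its call without replicate 2 of the unstressed vector, unstressed circDYM, CUS vector or CUS circDYM group (adjusted p = 0.0648, 0.101, 0.0829 and 0.117). Positive interactions include Gkn3, a gastrokine gene (2.53), Hes5 (1.84), Kdr (1.23) and Tek (0.88, adjusted p = 0.00773). In all, 92 genes were positive and 276 negative, 368 of 21233 by edgeR, and 131 and 242 by limma on FPKM. The count was 201 without unstressed vector replicate 2, 178 and 198 without unstressed circDYM replicates 1 and 3, 184 without CUS vector replicate 2, 181, 213 and 180 without CUS circDYM replicates 1, 2 and 3, and 1083 with DESeq2. Each gene named so far for the interaction passed in all 12 fits that left out 1 library, with Sgk1 again not followed. Of the 48 that the rule names here and that passed, 25 passed in all 12 fits and 23 lost the call in at least 1.

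**Figure D3:**
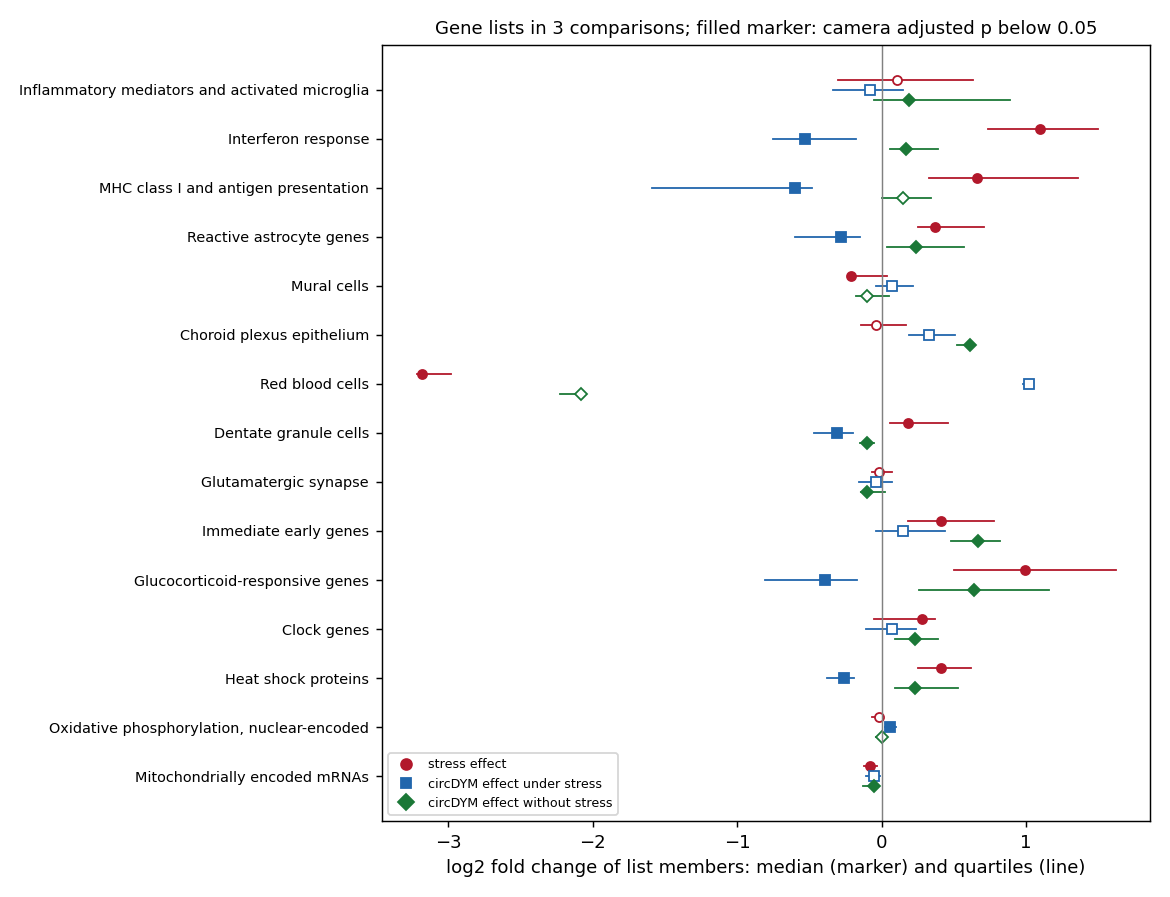
Median log2 fold change (horizontal axis) of each gene list called in at least 1 of 3 comparisons, with lines from the lower to the upper quartile of its genes, for stress and for circDYM EVs with and without stress. Filled points passed the camera test at an adjusted p of 0.05; the glucocorticoid-responsive list lies at 0.99 for stress, -0.39 for circDYM EVs under stress and 0.64 without stress.

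Averaged over both stress states, 104 genes were higher and 76 lower with circDYM EVs, and the split was 106 and 47 with limma on FPKM rescaled to a common sum and 89 and 83 on quantile-normalized FPKM. The average joins unlike effects, which had an r of -0.014 across genes and 8 higher and 0 lower genes in common. Immediate early genes had medians of 0.67 without stress and 0.15 under it, and glucocorticoid-responsive genes 0.64 and -0.39. Ch25h, named next, had an interaction of -3.71 on the log2 scale. Icam1 was higher by 2.67 ± 0.30 on the log2 scale (adjusted p = 0.0084), Ch25h was 5.30-fold higher (adjusted p = 0.00555) and Sele higher by 4.34 (adjusted p = 0.0102). Without unstressed vector replicates 1 and 3 the value for Sele was 7.08, which depends on the prior count because the remaining unstressed vector library had no reads of it. Immediate early genes had 9 of 25 members higher (18 higher and 1 lower adjusted over the list alone; median 0.45, camera adjusted p = 3.03e-17, and adjusted p = 0.103 with an estimated correlation). Dentate granule cell markers had 2 of 12 lower (8 adjusted over the list alone; median -0.20, camera adjusted p = 1.4e-06, and adjusted p = 0.458 with an estimated correlation). Markers of other cell types were called beside them. Neocortical neurons (median 0.16, camera adjusted p = 0.00667), choroid plexus epithelium (0.48, 0.00562), meningeal and perivascular fibroblasts (0.20, 0.0198) and GABAergic neurons (0.06, 0.0407) lay higher than other genes. CA3 pyramidal cells (-0.13, 0.0198), oligodendrocyte precursors (-0.09, 0.0415) and microglia identity (-0.08, 0.00562) lay lower. With an estimated correlation the adjusted p of these lists was between 0.616 and 0.85. Of their members 1 CA3 and 1 microglia marker passed, both lower, and adjusted over the list alone 3 neocortical markers were higher and 3 CA3, 1 precursor and 2 microglia markers lower. The choroid plexus call was lost without unstressed vector replicate 1 (adjusted p = 0.606) and the neocortical call without unstressed circDYM replicate 2 (0.0572). The CA3, fibroblast, GABAergic and precursor calls were lost in 4, 5, 8 and 8 of the 12 fits that left out 1 library, with adjusted p up to 0.0737, 0.41, 0.238 and 0.141. Camera also called MHC class I and antigen presentation (-0.23), glucocorticoid-responsive (0.12), clock (0.13), glutamatergic synapse (-0.07), inflammatory (0.05) and oxidative phosphorylation genes (0.03) and mitochondrially encoded mRNAs (-0.06). Their adjusted p was between 8.59e-06 and 0.0396, and between 0.103 and 0.834 with an estimated correlation. The synapse, inflammatory, oxidative phosphorylation and mitochondrial calls were lost in 3, 8, 3 and 4 of those 12 fits (adjusted p up to 0.141, 0.135, 0.144 and 0.41). The count of 180 genes was 85, 59, 52, 63, 89, 85, 67, 102, 53, 70 and 49 without unstressed vector replicates 1 and 2, unstressed circDYM replicates 1, 2 and 3, CUS vector replicates 1, 2 and 3 and CUS circDYM replicates 1, 2 and 3, in that order. DESeq2 called 708.

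Averaged over both EV types, 166 genes were higher and 53 lower in CUS than in unstressed libraries. The average joins 1312 calls under vector EVs with 0 by edgeR under circDYM EVs (973 at an unadjusted p under 0.05, limma on FPKM 0, DESeq2 22), and 7 of 100 splits of the libraries gave at least 219 genes, so chance cannot be excluded for this count. Glucocorticoid-responsive genes had 12 of 22 members higher (18 higher and 1 lower adjusted over the list alone; median 0.51, camera adjusted p = 1.12e-21, and adjusted p = 0.0733 with an estimated correlation), with Plin4 higher by 2.01 ± 0.16 (adjusted p = 0.00155) and Sgk1 by 0.69 (adjusted p = 0.0138) on the log2 scale. Interferon-response genes had 3 of 24 higher (19 adjusted over the list alone; median 0.73, camera adjusted p = 5.83e-16, and adjusted p = 0.238 with an estimated correlation). Heat shock proteins had 3 of 20 higher (12 adjusted over the list alone; median 0.18, camera adjusted p = 1.64e-13, and adjusted p = 0.0844 with an estimated correlation). Between the circDYM groups alone the medians were -0.04 for the glucocorticoid-responsive list (camera adjusted p = 0.359), -0.10 for heat shock proteins and 0.19 for interferon response. The glucocorticoid and heat shock averages thus come from the vector-treated libraries and show no rise across EV types. Lists of other cell types were called as well, with medians of -0.53 for leukocytes, -0.14 for neocortical neurons, -0.11 for microglia identity, -0.08 for mural cells and 0.10 for dentate granule cells. Their camera adjusted p was between 0.00332 and 0.0466, and between 0.453 and 0.527 with an estimated correlation. Of these the microglia call was kept in all 12 fits that left out 1 library, and the others were lost in 7, 5, 6 and 3 of them in the order given (adjusted p up to 0.299, 0.246, 0.09 and 0.185). Mitochondrially encoded mRNAs had a median of -0.08 (camera adjusted p = 0.000995, and adjusted p = 0.527 with an estimated correlation). The count of 219 genes was 93 without unstressed vector replicate 2, 62 and 98 without unstressed circDYM replicates 2 and 3, 67 without CUS vector replicate 2, and 97, 59 and 106 without CUS circDYM replicates 1, 2 and 3, and DESeq2 called 784.

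Genes that stress raised in vector-treated mice overlapped with genes that circDYM EVs lowered under stress. Of the 896 and 327 genes, 259 were shared, among them Plin4, Hsp90b1 and Sult1a1, where independent lists would share 13.8, and of the 416 genes that stress lowered and the 175 that circDYM EVs raised, 117 were shared, among them Hes5 and Kdr, where independent lists would share 3.4. These comparisons share the CUS vector libraries with opposite sign, which alone gives a negative correlation. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was -0.584 (Spearman's rho -0.567), against a mean of -0.5 and a range of -0.537 to -0.467 in 1000 simulations of unchanged groups. Without CUS vector replicate 2 it was -0.625, within the range of -0.634 to -0.566 simulated for that fit. The covariance was -0.144 against a simulated -0.0773. The number of genes called in both with opposite sign was 376 by edgeR. By limma on log2 CPM, the test run in the simulations, it was 374, against at most 1 in the simulations, in which genes varied independently. Of genes at an unadjusted p under 0.05 for stress in that test, 92.4% had the opposite sign with circDYM EVs under stress, against a simulated mean of 87.8% (84.0 to 90.95). Part of the excess may come from the shared controls, because 3 libraries cannot be divided into parts of at least 2. The 376 genes became 198 and 114 without CUS vector replicates 1 and 2, and 107, 159 and 104 without CUS circDYM replicates 1, 2 and 3.

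Stress and circDYM EVs without stress, which share the unstressed vector libraries, had 83 higher genes in common, Sgk1, Lcn2 and Fos among them, and 17 lower genes in common, where independent lists would share 4.7 and 0.5. Their r was 0.546 (rho 0.494), against a simulated mean of 0.499 (0.461 to 0.539), and the covariance was 0.137 against 0.0771. The share of same signs went the other way: of genes at an unadjusted p under 0.05 for stress, 83.91% had the same sign with circDYM EVs without stress, below the simulated mean of 87.69% and the lowest simulation (83.98%). The effects of circDYM EVs with and without stress share no library, and their log2 fold changes had an r of -0.014 across genes (rho -0.027), within the simulated range of -0.0498 to 0.0607. They had 8 higher genes in common, and 15 genes were lower under stress and higher without it, where independent lists would share 0.9 and 1.7. The 8 genes became 4 without unstressed vector replicate 1 or 2 or unstressed circDYM replicate 2, 5 without unstressed circDYM replicate 3, 3, 2 and 2 without CUS vector replicates 1, 2 and 3, and 2, 4 and 1 without CUS circDYM replicates 1, 2 and 3.

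Taf1, which encodes the largest subunit of the TFIID transcription factor and whose protein has been linked to circDYM (ENSMUSG00000031314, chromosome X, 101532734 to 101601789), lay at 68.7, 66.3, 65.4 and 74.4 CPM in the unstressed vector, unstressed circDYM, CUS vector and CUS circDYM groups. It passed in no comparison (adjusted p = 0.85 for stress, 0.584 for circDYM under stress, 0.933 without stress and 0.647 for the interaction). The TFIID subunits as a list did not pass either, with medians of 0.10 for stress (camera adjusted p = 0.0722; 3 of 17 higher adjusted over the list alone) and -0.05 for circDYM under stress (adjusted p = 0.456). Over the markers of microglia identity, stress raised 3 of 22 and lowered 3 (3 and 5 adjusted over the list alone, median -0.12, camera adjusted p = 0.192), with the receptor gene Gpr34 1.58-fold lower (adjusted p = 0.0022). Among 22 monoamine receptors 3 rose with stress (3 higher and 1 lower adjusted over the list alone; median 0.02, camera adjusted p = 0.544), including the serotonin receptor gene Htr1a, from 35.6 to 49.0 CPM (1.38-fold, adjusted p = 0.00346).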

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

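The test of time of day, the test of a handling difference with the pairs of groups it rests on, and the fit without unstressed vector replicates 1 and 3 were chosen only after the data were seen, and the other tests in this part were planned before. The results below were singled out because the effect of circDYM EVs differed between stressed and unstressed mice by the interaction test of edgeR. That test called 368 genes, and 1 of 100 splits of the libraries gave as many, the real one. The highest of the others gave 180, so a chance division of these libraries can be excluded at a share of 0.05. The splits treat libraries as independent units, which the labels do not state, so a chance difference between groups of mice stays possible. They exchange EV labels within each stress state, so they test against no EV effect in either state. The split with 180 genes exchanges the EV labels in 1 stress state and so measures the average effect.

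On the log2 scale the interaction was 2.53 for Gkn3, 1.86 for Plcxd1, 1.84 for Hes5, 1.47 for Rnf8, 1.45 for Rxrg, 1.39 for Pla2g4e, 1.26 for Cirbp, 1.23 for Kdr, 1.22 for Degs2 and 1.17 for Opalin. It was -5.93 for Lcn2, -4.40 for Selp, -4.28 for Plin4, -3.71 for Ch25h, -3.50 for Gbp5, -3.22 for Tgtp1 and -2.96 for Gbp2. For Scgb3a1 (-11.69) and Ccl8 (-10.23), which had 0 counts in unstressed vector libraries, and for Serpina3f (-7.48), the fitted values depend on the prior count and are no bounds. Without unstressed vector replicate 3 the value was -7.10 for Lcn2 and -12.54 for Serpina3f, which was -6.89 without unstressed vector replicate 2 and -6.76 without unstressed circDYM replicate 1. It was -14.78 for Scgb3a1 without CUS circDYM replicate 3, -13.76 and -9.64 for Ccl8 without CUS circDYM replicates 2 and 3, and -2.35 for Gbp2 without CUS vector replicate 2. Of the 48 genes that the rule names for the interaction and that passed, 25 passed in all 12 fits without 1 library. Gbp2 and Tgtp1 passed in 1 of those fits each, Gbp5 in 2, Selp and Pla2g4e in 3, Ccl8 and Rxrg in 4, Rnf8 in 5 and Degs2 in 0 (adjusted p between 0.057 and 0.112). Their highest adjusted p was 0.111, 0.084, 0.0886, 0.0983, 0.0956, 0.0806, 0.0763, 0.0806 and 0.112 in that order. Cirbp lost its call without CUS circDYM replicates 1 and 2, unstressed circDYM replicate 3 and unstressed vector replicate 2 (adjusted p = 0.056, 0.0619, 0.0525 and 0.055), and Opalin without CUS vector replicates 1 and 2, unstressed circDYM replicate 1 and unstressed vector replicate 2 (adjusted p = 0.0525, 0.0633, 0.0573 and 0.0519).

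The medians of the lists were -1.14 for glucocorticoid-responsive genes, -0.82 for MHC class I and antigen presentation, -0.71 for interferon response, -0.51 for heat shock proteins, -0.49 for reactive astrocyte genes, -0.46 for immediate early genes and -0.19 for clock genes. With an estimated correlation, adjusted p stayed past the threshold for the glucocorticoid-responsive and heat shock lists (0.0297 each). As edgeR called 0 genes between the circDYM groups, these medians largely mirror the stress effect under vector EVs.

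The first pattern is that 376 genes changed by stress moved back with circDYM EVs under stress. Noise of the shared CUS vector libraries gave at most 1 such gene in 1000 simulations with independent genes tested by limma on log2 CPM. That test called 374 in the data. The simulated groups had no effect, so this argues only against noise without any effect. It cannot show what part of the overlap the shared libraries give. Of genes at an unadjusted p under 0.05 for stress, 92.4% had the opposite sign, against at most 90.95% in the simulations. The r of stress against circDYM under stress lay within its simulated range without CUS vector replicate 2. Without unstressed vector replicates 1 and 3, which leaves a lone library, it was -0.431, beyond the -0.388 to -0.318 simulated for that fit. This argues against those libraries as the whole cause. The CUS vector group differed from each other group by at least 489 genes, while the other groups differed among themselves by at most 136, as they would if the CUS vector mice or samples had been handled differently. Since that handling, if any, would follow the group, it cannot be told apart from an effect of stress that circDYM EVs lessen, and both may contribute.

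The second pattern is that glucocorticoid-responsive and immediate early genes were higher with circDYM EVs without stress. Noise of the shared unstressed vector libraries gave at most 1 gene in common with stress in the simulations. The same test, limma on log2 CPM, gave 110 in the data. The simulated groups had no effect, so this argues only against noise without any effect. It cannot show what part of the overlap the shared libraries give, and it covers all genes, not these lists alone. Of genes at an unadjusted p under 0.05 for stress, 83.91% had the same sign, no more than the 83.98% to 91.19% simulated. Without 1 of the unstressed libraries, which alone enter this comparison, the median of the glucocorticoid list ran from 0.579 to 0.78. This argues against a single deviating library. Fits without a CUS library bear on it only through the shared spread, the genes kept and the scaling, and gave 0.63 to 0.638. A different time of day at dissection might raise both lists, and the clock list was itself higher (median 0.23, 14 of 16 positive, camera adjusted p = 4.38e-07, and 0.0405 with an estimated correlation), with Per1 1.53-fold higher. The 95% intervals of the clock genes Dbp (0.10, from -0.09 to 0.29) and Arntl (-0.10, to -0.335 at most) stay below the glucocorticoid list median of 0.64, but these 2 genes do not decide against the rise of their list, and time of day stays open. Differences in handling stress before dissection follow the group and were not tested, so a biological effect of circDYM EVs stays a hypothesis.

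The 6 libraries of a comparison of 2 groups can be divided in 10 ways, too few for a share under 0.05. The real value and the highest other were 1312 and 4 genes for stress, 502 and 3 for circDYM under stress, and 136 and 2 for circDYM without stress, with 1 split, the real one, at each real value. For circDYM averaged over stress states, 2 of 100 splits gave at least 180 genes. A chance division of these libraries can be excluded, again only if the libraries are independent. The highest other gave 368 and is the interaction. For stress averaged over EV types, 7 of 100 splits gave at least 219 genes, the highest other 415, and chance cannot be excluded. Its 6 larger splits keep the labels of the vector-treated libraries and reshuffle the circDYM-treated ones, a structure of the samples that follows the CUS vector group.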

How the results depend on the processing

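The fit without unstressed vector replicates 1 and 3 and the choroid plexus covariate were chosen only after the data were seen, and the other alternatives were planned. Counts of calls moved more than the directions of the named genes and called lists did. Most of these were picked for a large fold with separated libraries, a low p or a call. Few reversals among them were therefore likely from the start and do not describe genes at large. Over the named genes and their alternatives, 7905 values kept direction and side of the threshold, 1141 lost the call, 164 gained one and 22 reversed, and over the called lists 1464 kept the call, 241 lost it and 6 reversed. Alternatives on pseudocount, quantile normalization and robust fitting apply to limma on FPKM and so change the test as well, and DESeq2 gives no camera test. Another scaling moved the median of all genes by at most 0.031 on the log2 scale. At 37140657 counts or more per library, depth limits mainly genes near 0 counts, such as Scgb3a1 and Ccl8. Except where stated, the cause of a change was not tested.

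With no filter on low values, which tests more genes, the calls were 862 for stress, 290 for circDYM under stress, 235 for the interaction, 71 and 112 for the circDYM and stress averages, 226 genes opposite in stress and circDYM under stress, 3 shared by both circDYM comparisons, and 17 lists without stress. With median centring they were 321 under stress, 75 for the circDYM average, 3 shared genes and 11 lists for the interaction. DESeq2 called 2178 for stress, 1247 under stress, 551 without stress, 1083 for the interaction, 708 and 784 for the averages, 841 opposite and 36 shared genes. The 6 compared libraries alone, a fit with fewer residual degrees of freedom, gave 434, 178 and 25 for stress and for circDYM under and without stress. An unadjusted p of 0.05 with a 2-fold change gave 626 for stress, 347 without stress and 691 for the interaction. The estimated correlation left 2 lists for stress, 0 under stress, 4 without stress, 2 for the interaction and 0 for both averages.

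Without unstressed vector replicates 1 and 3, which leaves a lone library assumed to vary like the other groups, calls were 483 for stress, 52 without stress, 199 for the interaction, 60 and 115 for the circDYM and stress averages, 181 opposite and 1 shared. With the choroid plexus covariate they were 83 without stress, 65 for the circDYM average and 4 shared.

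The replicate numbers do not pair the libraries: residuals of the 18 same-number pairs correlated between -0.094 and 0.05, with 0 of them over 0.1, and 1 of 12 libraries correlated best with its own number. The fit with the replicate block, which spends degrees of freedom, called 258 genes under stress, 73 without stress, 225 for the interaction, 45 and 88 for the circDYM and stress averages, 210 opposite and 2 shared, and 932 for stress.

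Leaving out 1 library gave 621 to 1102 calls for stress, 117 to 544 for circDYM under stress, 67 to 172 without stress, 178 to 304 for the interaction, 49 to 176 and 59 to 170 for the averages, 104 to 350 opposite and 1 to 12 shared genes, with fewer samples in each fit. The libraries that moved these counts by over 1.5 times are named beside each comparison. The r of stress against circDYM under stress ran from -0.656 to -0.518, and only without CUS vector replicate 2 (-0.625) did it lie within its simulated range. The r of both circDYM effects ran from -0.014 to 0, and was 0.004 over genes called in at least 1 of them. Called lists numbered 10 to 15 for stress, 7 to 12 under stress (12 without CUS vector replicate 2, 11 without CUS circDYM replicate 1), 9 to 19 without stress (19 without unstressed vector replicate 3), 7 to 11 for the interaction (11 without unstressed vector replicate 1 or 3 or CUS circDYM replicate 1), 8 to 16 for the circDYM average (8 without unstressed vector replicate 1, 10 without unstressed circDYM replicate 2) and 10 to 17 for the stress average.

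These results reversed, none past the threshold afterwards. For circDYM without stress, the choroid plexus list had adjusted p from 4.17e-10 without unstressed vector replicate 2 to 0.986 without replicate 1, 0.181 without replicates 1 and 3 and 0.93 with the covariate, which removes it by construction, and mitochondrially encoded mRNAs from 2.22e-05 without replicate 3 to 0.986 without replicate 1. For the circDYM average without both, meningeal fibroblasts had 0.991 and choroid plexus 0.654. For circDYM without stress, the choroid plexus genes Car12 (-0.005 and -0.035), Enpp2 (-0.275 and -0.004) and Kl (-0.3 and -0.097) reversed without both and with the covariate, and Kcnj13 (-0.064) without both. Fmo1 had 0.009 for the interaction without both. Dym, called nowhere, had -0.008 without unstressed vector replicate 1 and -0.099 without both for stress. It had 0.007 on rescaled FPKM, -0.072 to 0.052 without 1 library (0.052 without unstressed vector replicate 2) and 0.004 without unstressed circDYM replicate 2 for circDYM without stress. For the interaction it had 0.001 with quantile normalization, -0.106 to 0.018 without 1 library (0.018 without unstressed vector replicate 1), 0.008 without CUS circDYM replicate 3, 0.113 without both and 0.012 with the covariate. Taf1, also called nowhere, had 0.118 for stress without both, -0.029 (without CUS circDYM replicate 2) to 0.304 under stress, and -0.148 to 0.022 (without unstressed vector replicate 1) without stress, with 0.144 without both.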

Other observations

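The tests of leukocytes and of vessel cells, the choroid plexus covariate, the fit without unstressed vector replicates 1 and 3, the comparison of the circDYM groups, and the GO and KEGG terms and the genes named from them were chosen only after the data were seen. Of 23 tested genes of the GO term sterol biosynthetic process, 4 were higher with circDYM EVs averaged over stress states, where 0.15 are expected (adjusted p = 0.0293). They are Ch25h, a hydroxylase gene that acts on cholesterol, and 3 genes of cholesterol synthesis. Fdft1, the squalene synthase gene, averaged 55.9 and 77.4 CPM in unstressed vector and unstressed circDYM libraries and 54.6 and 75.6 CPM in CUS vector and CUS circDYM libraries (log2 fold change 0.47 ± 0.08 SE, n = 6 libraries against 6, adjusted p = 0.0268). Cyp51, the lanosterol demethylase gene, was higher by 0.24 ± 0.04 (adjusted p = 0.0338) and Hmgcs1, the HMG-CoA synthase gene, by 0.17 ± 0.03 (adjusted p = 0.0359). Hmgcs1 also fell with stress, from 220 to 182 CPM (-0.27 ± 0.04, adjusted p = 0.00498), and rose with circDYM EVs under stress, to 229 CPM (0.33 ± 0.04, adjusted p = 0.00524). Its interaction was 0.32 (adjusted p = 0.0259).

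Of 15 tested genes of the GO term protein disulfide isomerase activity, the forming and exchange of disulfide bonds, 5 were lower with circDYM EVs under stress, where 0.30 are expected (adjusted p = 0.0169), and 10 were not called lower. Pdia4 averaged 37.9, 54.4, 79.4 and 49.3 CPM in the unstressed vector, unstressed circDYM, CUS vector and CUS circDYM groups (n = 3 libraries each). It fell by 0.69 ± 0.10 on the log2 scale with circDYM EVs under stress (adjusted p = 0.00909) after a rise of 1.07 ± 0.10 with stress (adjusted p = 0.000422), and its interaction was -1.21 (adjusted p = 0.00372). Pdia6 (-0.65 ± 0.09, adjusted p = 0.00613), Pdia3 (-0.48 ± 0.08, adjusted p = 0.0159), Creld2 (-0.64 ± 0.09, adjusted p = 0.00581) and Creld1 (-0.30 ± 0.05, adjusted p = 0.0205) fell as well. Among the genes that stress lowered, the KEGG Ras signalling pathway held 16 where 5.02 are expected (adjusted p = 0.0111), with Kdr, Tek, Vegfc, Pdgfrb, Bdnf and Met among them.

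Between the CUS circDYM and unstressed circDYM groups, where edgeR called 0 genes (973 at an unadjusted p under 0.05, limma on FPKM 0, DESeq2 22), camera still called lists. Leukocyte markers had a median log2 fold change of -1.62 (adjusted p = 0.00041, and adjusted p = 0.703 with an estimated correlation), heat shock proteins -0.10 (adjusted p = 0.000455, and adjusted p = 0.703), microglia identity -0.12 (adjusted p = 0.00145, and adjusted p = 0.703) and interferon response 0.19 (adjusted p = 0.00147, and adjusted p = 0.797). Immediate early genes (-0.15, adjusted p = 0.00184), inflammatory mediators (-0.28, adjusted p = 0.0157), meningeal and perivascular fibroblasts (-0.35, adjusted p = 0.0308), MHC class I and antigen presentation (-0.20, adjusted p = 0.0327) and mitochondrially encoded mRNAs (-0.05, adjusted p = 0.0327) were lower too, with adjusted p between 0.556 and 0.797 with an estimated correlation. The heat shock, immediate early and MHC lists were higher with stress under vector EVs.

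A pattern in the circDYM average is that 8 genes of the TNF pathway were higher (Icam1, Il1b, Sele, Tnfaip3, Cxcl1, Fos, Vcam1 and Nfkbia; lowest log2 fold change 0.61, median 1.57), where 0.83 are expected (adjusted p = 0.000407). The calls differed between the stress states: all 8 passed without stress and only Il1b under stress (1.71 ± 0.38, adjusted p = 0.0421). Vcam1 did not pass without stress when unstressed vector replicate 1 or unstressed circDYM replicate 1 was left out (adjusted p = 0.0655 and 0.0561). Il1b lost its call under stress in 10 of the 12 fits without 1 library, with adjusted p up to 0.137. Under stress Fos was at 0.05 ± 0.15 (adjusted p = 0.924) and Nfkbia at 0.02 ± 0.17 (adjusted p = 0.978). Of the 8 these 2 passed for the interaction (-1.46 and -1.18, adjusted p = 0.00814 and 0.0334), Fos in all 12 of those fits and Nfkbia in 5, with adjusted p up to 0.0905. The other genes did not pass for the interaction, so a smaller rise under stress was not shown for them. Their missing calls under stress do not mean that they did not rise there. A larger share of vessel cells would raise the endothelial markers as much, but their upper quartile was 0.145, below the lowest of the 8, and with the choroid plexus covariate 7 of the 8 still passed and Nfkbia went from 0.61 ± 0.12 (adjusted p = 0.0435) to 0.52 ± 0.10 (adjusted p = 0.0616), which argues against that share and against uneven choroid plexus content as the whole cause. Without unstressed vector replicates 1 and 3, a fit with fewer samples that leaves out the library low in choroid plexus RNA, 4 of the 8 passed and the call ended for Cxcl1 (3.65 ± 0.49 to 3.30 ± 0.56, adjusted p = 0.0635), Fos (0.78 ± 0.11 to 0.85 ± 0.14, adjusted p = 0.0502), Vcam1 (0.90 ± 0.14 to 0.79 ± 0.17, adjusted p = 0.114) and Nfkbia (to 0.62 ± 0.12, adjusted p = 0.0801), 4 folds that moved by less than their SE, while Sele went from 4.34 ± 0.55 to 7.08 ± 0.78, a value that depends on the prior count. More leukocytes in the tissue may contribute, since the upper quartile of their 16 tested markers was 0.969, above the lowest of the 8, while the median was 0.10, and few counts per marker keep this open, and no biological explanation was tested.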
